A study of Mus musculus with 6 samples.

How the data were processed

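Poly(A)-captured RNA of HCC3-4 cells, a mouse liver tumour line from MYC transgenic animals, was sequenced in 6 libraries. The labels put 3 libraries in the group with a stable short hairpin RNA against Sf3b3 (KD) and 3 in the group with the pLKO.1-TRC control (PLKO), and number them 1 to 3 in each group. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

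The authors deposited 1 table with a value per gene and library for 11866 genes. Per the submitters' processing notes the genome build was GRCm38 and FastQC 0.11.7 was run. The aligner, the counter, the use of strand and the filter that left 11866 genes are not given in the sources used here. The deposited values are log2 FPKM (fragments scaled by gene length and library size), as read from the values themselves, which run from -7.85 to 13.17. Powers of 2 of the values sum to between 276049 and 310686 per library. The low values hold a prior: 21 genes share exact floors across libraries (tolerance 1e-07), and the steps above these floors match, with base 2, whole reads added to a prior with a mean of 2.0 reads per library (largest deviation 3e-08 reads).

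Read counts were recovered from these steps. With the exonic length of each gene in GENCODE M21, 11197 genes gave whole reads in all 6 libraries within a tolerance of 0.01 reads, and for the other 669 genes a scan over lengths found one that did so, which makes 100% of the genes. Reads on listed genes came to 16987626, 17463788 and 16179939 in PLKO 1, 2 and 3 and to 15140441, 16010622 and 17566101 in KD 1, 2 and 3, a 1.16-fold range. The library sizes behind the deposited values stood to these sums in ratios that differed between libraries (reads over library size 0.938 to 1.04), so a scaling factor per library had been applied before deposit. The recovered reads are given as depth and entered alternatives, not the main test. Since a prior was added before the logarithm, fold changes of genes with few reads are understated. Where a group held at most 10 reads of a named gene, the ratio of reads per scaled library is given with an exact 95% binomial interval, which covers counting error only.

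The main test was limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean-variance trend on the deposited log2 values as they stand, without another pseudocount or scaling, on the 10770 genes with a mean FPKM of at least 1. The other 1096 genes were not tested. The model held the group alone, with 4 residual degrees of freedom, and Benjamini-Hochberg adjusted p-values under 0.05 were called. The plan written before the data were examined had assumed linear FPKM and a log2(FPKM + 1) scale. Because the table already held logarithms, the deposited scale became the main one and log2(FPKM + 1) was run as an alternative. FPKM in the text are powers of 2 of the deposited values, given as mean ± SD over 3 libraries. Log2 fold changes are KD minus PLKO, with their standard errors (SE).

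For gene groups, 33 lists were fixed before the data were examined. The 29 lists with at least 5 tested members were tested with limma's camera against all other tested genes, with a preset correlation of 0.01 between genes and adjustment over the lists. Each test was repeated with an estimated correlation and with fry. The other 4 lists are described only. Calls within a list are given over all genes tested and adjusted over the list alone. Genes were named by a rule fixed at the same time: Sf3b3, Nr1h4 and Myc, the 10 genes with the largest and the 10 with the smallest fold change among called genes whose groups do not overlap (predicted genes left out), every SF3b gene, and up to 4 tested members of each other list with the lowest adjusted p. Not every gene that the rule takes is reported here. Genes named outside this rule are marked as chosen after their values were seen. Coordinates are 1-based on GRCm38 from GENCODE M21, in which 99.4% of the listed symbols matched 1 gene.

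Whether equal numbers pair the libraries was checked with the deviations from the group means over genes. The correlations were 0.18, 0.29 and 0.50 for the pairs numbered 1, 2 and 3, all above the limit of 0.1 set beforehand, so the numbers were taken to pair the libraries. This pairing comes from the data and not from a label. It is not clean: PLKO 1 correlated with KD 2 at 0.27 and PLKO 2 with KD 1 at 0.30. Deviations cancel within a group, so the likeness of PLKO 3 and KD 3 alone can raise the correlations between libraries 1 and 2. The limit therefore could not show whether equal numbers pair libraries 1 and 2. Fits with the block rest on an assumed pairing. A fit with the replicate number as a block is given beside results where it changes a call or moves a count by more than 1.5 times.

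The scripts were tested on simulated data with the 10770 tested genes and 200 genes changed. The fit recovered 28% of the genes changed 2-fold and 70% of those changed 4-fold, and called 5 unchanged genes among 105 calls. A simulated list shifted by 0.8 was called, and 0 of 20 unshifted lists were. Genes were simulated independently of each other, so this does not test list calls where genes of a list move together. Alternatives fixed before the data were examined covered the pseudocount, the filter, the scaling, the trend, robust variances, array weights, the replicate block, each library left out in turn, and the set test. Those added later were the log2(FPKM + 1) scale, limma-voom on the recovered reads with and without quality weights and with scaled or total library sizes, leaving out both libraries numbered 3, and removal of trends with exonic length, exon number and GC content (known for 99.4% of tested genes), alone or with the replicate block. Gene-level values hold no isoforms, so splicing was not analysed here.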

Results

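Gene expression was measured by RNA-seq in HCC3-4 cells, a mouse liver tumour line derived from MYC transgenic mice, with 3 Sf3b3 knockdown (KD) and 3 vector control (PLKO) libraries. Sf3b3 encodes a subunit of SF3b, the part of the U2 small nuclear ribonucleoprotein that binds at the branch point of introns. Between 15140441 and 17566101 reads fell on the 11866 listed genes of each library, and 10770 genes were tested. The series concerns splicing of the bile acid receptor FXR (Nr1h4) by SF3B3 in liver cancer driven by MYC. The comparison of KD with PLKO asks which transcript levels differ between the knockdown and the control cells. No label names a second hairpin or a rescue. Effects of lower Sf3b3 therefore cannot be told apart from other effects of the hairpin or from other differences between the cell populations.

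Sf3b3 fell in the KD cells, from 26.9 ± 3.67 FPKM (SD, n = 3) in PLKO to 11.3 ± 2.33 FPKM in KD, a log2 fold change of -1.26 (SE 0.23). The limma adjusted p was 0.037. Relative to the PLKO mean, Sf3b3 stood at 38.4%, 35.6% and 51.8% in KD 1, 2 and 3, and at 84.3%, 107% and 109% in PLKO 1, 2 and 3. Relative to the PLKO library of the same number it stood at 45.6%, 33.3% and 47.7%. The gene (ENSMUSG00000033732.10) lies on chromosome 8 from 110810239 to 110846787 on the minus strand, has 23 exons and overlaps Cog4 on the opposite strand. It was covered by 4472, 5243 and 5046 reads in PLKO and by 1740, 1651 and 2666 in KD. The exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow. Without PLKO 1, PLKO 2, KD 1 or KD 2 the limma adjusted p of Sf3b3 was 0.13, 0.13, 0.15 and 0.19, with log2 fold changes of -1.38, -1.21, -1.21 and -1.15.

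Nr1h4, which encodes FXR, had 4.35 ± 0.285 FPKM in PLKO and 3.73 ± 0.334 FPKM in KD (n = 3 each), a log2 fold change of -0.23 with a 95% confidence interval from -0.74 to 0.29 and a limma adjusted p of 0.54. Over 24 alternatives its log2 fold change ran from -0.42 to -0.07, and it was called lower in 1 of them (limma adjusted p = 0.020). The gene lies on chromosome 10 from 89454234 to 89533585. Myc, on chromosome 15 from 61985391 to 61990374, had 46.2 ± 36.3 FPKM in PLKO and 17.6 ± 11.3 FPKM in KD. Its log2 fold change of -1.29 (interval -2.58 to 0.01) did not pass the test (limma adjusted p = 0.18), and its reads ranged from 819 to 3972 in PLKO and from 413 to 1456 in KD. Without PLKO 2 it was -0.68 (adjusted p = 0.43) and without both libraries numbered 3 it was -2.27 (adjusted p = 0.0062). Myc was called lower in that fit, with array weights (adjusted p = 0.00060) and with voom and quality weights (-1.53, or -1.56 with total library sizes), and its adjusted p ran up to 0.46 over all alternatives.

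Sf3b3 was the 1 SF3b gene of 7 called over all genes, and Sf3b1 was called with the replicate block. Sf3b1, the subunit that holds the branch point helix, had 35.8 ± 3.93 FPKM in PLKO and 71.1 ± 15.3 FPKM in KD, a log2 fold change of 0.97 (SE 0.22) with a limma adjusted p of 0.054, and 0.016 with the replicate block. Sf3b5, Sf3b4, Sf3b2, Phf5a and Sf3b6 had log2 fold changes of 0.73, 0.26, 0.21, 0.02 and 0.00, with limma adjusted p from 0.14 to 0.99. Adjusted over the list alone, Sf3b1 was called higher and Sf3b3 lower.

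**Figure D1:**
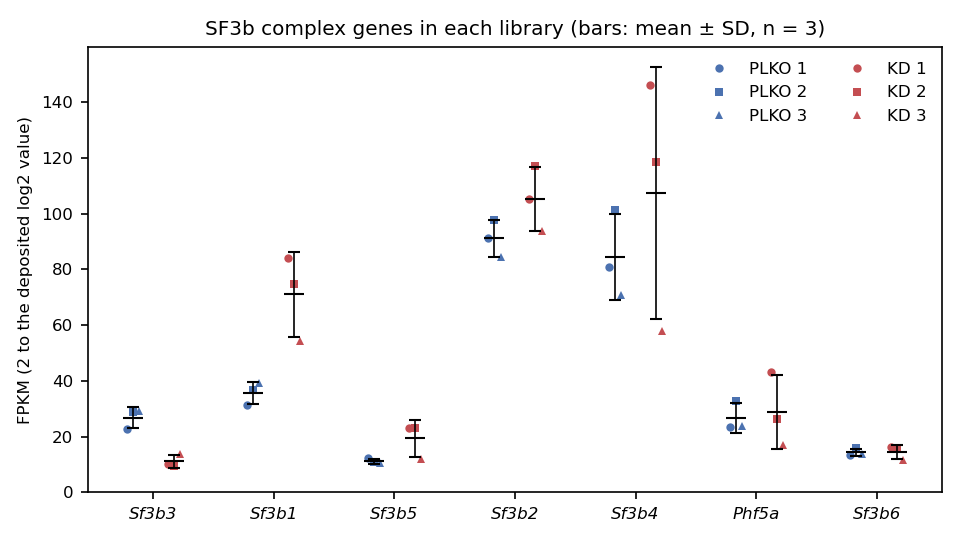
FPKM of the 7 SF3b genes in each PLKO (blue) and KD (red) library, with marker shapes for the library number and black bars for the mean ± SD (n = 3). Sf3b3 averages 26.9 FPKM in PLKO and 11.3 FPKM in KD, and Sf3b1 35.8 and 71.1 FPKM.

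In all, 314 of the 10770 tested genes changed (limma adjusted p under 0.05), 121 higher and 193 lower in KD, and 297 of them at least 2-fold. With the replicate block 2080 of the 10770 genes were called (882 higher, 1198 lower, 1088 at least 2-fold), all 314 among them. Counts with the block in the lists below stand beside that share and were not tested against it. The groups did not overlap for 3460 genes, 32.1% of those tested, where chance gives 10% for a single gene. Genes are not independent and share the structure of the same 6 libraries, so the excess over 10% was not tested. No gene was called by limma without PLKO 1, PLKO 2, KD 1 or KD 2 (2208, 2321, 1813 and 1783 genes at an unadjusted p under 0.05), whereas 802 were called without PLKO 3, 1751 without KD 3 and 3000 without both. This dependence on single libraries covers each called gene named in the report.

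Genes that rose most in KD had few or no reads in the control cells. Lcp1, an actin-bundling protein of leukocytes that many tumour cells express, went from 0.104 ± 0.0536 to 2.17 ± 0.474 FPKM (log2 fold change 4.48, SE 0.62, limma adjusted p = 0.030). Mmp10, a matrix metalloproteinase, went from 0.754 ± 0.732 to 13.3 ± 9.68 FPKM (4.30, SE 0.86, adjusted p = 0.043). Trim69, a tripartite motif protein, and Lrp11, an LDL receptor related protein, had log2 fold changes of 3.73 (SE 0.50) and 3.49 (SE 0.42), and Cd79a, a B cell receptor component, and Tmem171 of 3.77 and 3.47. Colec11, a collectin, had 4 reads in PLKO and 287 in KD, a ratio of 74.4 with a 95% counting interval from 28.8 to 275. Crct1 had 4 and 75 reads (ratio 19.5, interval 7.29 to 73.2). Rasl2-9, a gene that closely resembles Ran, had 4 and 105 reads (27.2, interval 10.3 to 101.8) and can share reads with it. The microRNA gene Mir3091 had 3 and 128 reads (44.3, interval 14.8 to 217), but lies inside Rps21 on the same strand, so those reads can belong to Rps21. The limma adjusted p of these 10 genes ran from 0.022 to 0.047. On the log2(FPKM + 1) scale Lcp1, Mmp10, Trim69, Lrp11, Cd79a, Tmem171, Colec11, Crct1 and Rasl2-9 had log2 fold changes from 1.29 (Crct1) to 2.80 (Mmp10), with limma adjusted p from 0.027 to 0.042.

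Slc7a5, Gpt2 and Atf5 were among the 10 genes with the largest fall. Slc7a5, the large neutral amino acid transporter LAT1, fell from 209 ± 27.9 to 49.5 ± 9.68 FPKM (log2 fold change -2.09, SE 0.22, limma adjusted p = 0.014). It lies on chromosome 8 from 121881150 to 121907694. Gpt2, the mitochondrial alanine transaminase on the same chromosome (85492576 to 85527560), fell from 68.6 ± 14.1 to 14.4 ± 3.17 FPKM (-2.26, SE 0.24, adjusted p = 0.014). Atf5, a transcription factor of the stress response, fell from 152 ± 74.3 to 22.5 ± 7.09 FPKM (-2.70, SE 0.35, adjusted p = 0.029). It overlaps Nup62 and Il4i1 on the opposite strand. Aldh1l2, an enzyme of mitochondrial folate metabolism, and Pycr1, which makes proline, had log2 fold changes of -2.50 (SE 0.40) and -2.19 (SE 0.39). Acox2, a peroxisomal oxidase of bile acid intermediates, fell by 2.81 (SE 0.58) and Dgat2, which completes triglyceride synthesis, by 2.27 (SE 0.34) on the log2 scale. Nxph4, a neurexophilin, fell by 2.28 (SE 0.33), the interferon-induced gene Ifi44 by 2.17 (SE 0.45) and the glucuronosyltransferase gene Ugt1a6b by 2.03 (SE 0.45), although Ugt1a6b shares exons and reads with the other genes of its cluster. The limma adjusted p of these 10 genes ran from 0.014 to 0.0498. On the log2(FPKM + 1) scale Acox2, Ifi44 and Ugt1a6b fell by 1.55, 1.26 and 1.07 (adjusted p from 0.034 to 0.042).

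**Figure D2:**
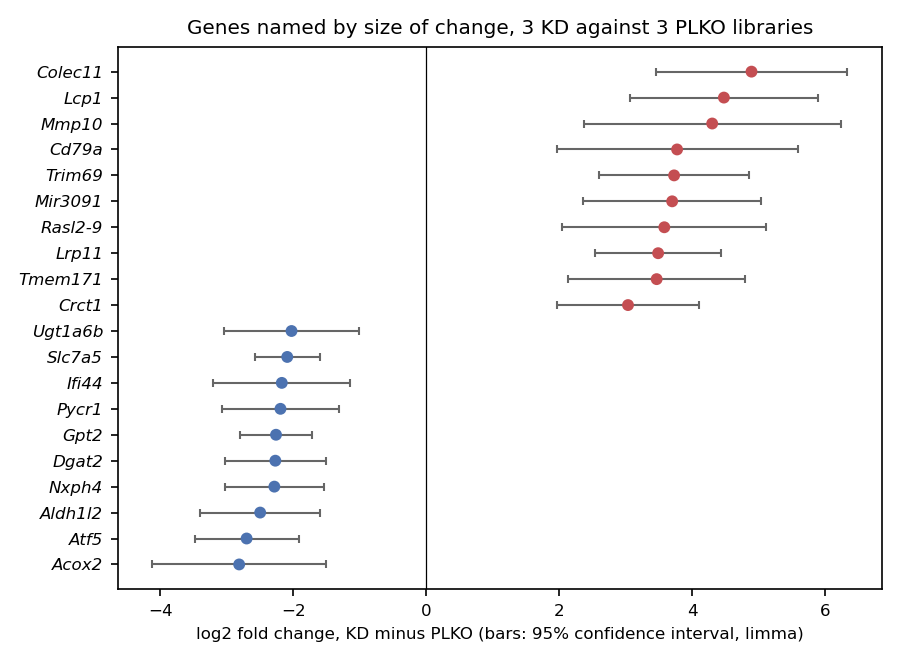
Log2 fold change (KD minus PLKO, x axis) of the 10 genes named for the largest rise (red) and the 10 for the largest fall (blue), with 95% confidence intervals from limma over 3 against 3 libraries. Values run from -2.81 (Acox2) to 4.89 (Colec11), and no interval reaches 0.

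Immediate early genes, which cells switch on within minutes of a stimulus, were shifted upward as a list. Of 25 tested members 20 were higher in KD, with a median log2 fold change of 0.73 (camera adjusted p = 0.00040 with the preset correlation, adjusted p = 0.92 with an estimated correlation). Fosb, with 148, 146 and 171 reads in PLKO and 751, 671 and 1061 in KD, rose by 2.43 on the log2 scale (SE 0.26, limma adjusted p = 0.014), the 1 member called over all genes. Adjusted over the list alone, 10 members were higher and 1 lower, and with the replicate block 12 and 1. Maff, Nr4a1 and Egr1 had log2 fold changes of 1.97, 0.93 and 2.63, with limma adjusted p of 0.050, 0.063 and 0.071 (0.0026, 0.022 and 0.0010 with the replicate block). Without KD 3 the median was 0.57 and the camera adjusted p 0.054.

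The list of the unfolded protein and integrated stress response, genes of protein folding in the endoplasmic reticulum and of amino acid shortage, was shifted downward. Of its 24 tested members 23 were lower, with a median log2 fold change of -0.62 (camera adjusted p = 0.0013, adjusted p = 0.92 with an estimated correlation). Pdia4, a disulfide isomerase, fell from 66.2 ± 8.08 to 28.8 ± 6.15 FPKM (-1.22, SE 0.22, limma adjusted p = 0.038) and Sdf2l1, an endoplasmic reticulum chaperone partner, from 61.2 ± 23.9 to 21.8 ± 6.27 FPKM (-1.47, SE 0.32, adjusted p = 0.049). These were the 2 members called, against 4 adjusted over the list alone and 9 with the replicate block. Sel1l and Psat1 had log2 fold changes of -0.81 and -0.67 (limma adjusted p = 0.071 and 0.075, and 0.029 and 0.045 with the block).

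A further pair of lists passed the camera test. Cholesterol synthesis genes had a median log2 fold change of 0.48, with 19 of 22 members higher (camera adjusted p = 0.0099, adjusted p = 0.92 with an estimated correlation), but no member was called over all genes or adjusted over the list alone, and 5 were with the replicate block. Fdps, Hmgcs1 and Lss had log2 fold changes of 1.94, 1.59 and 0.65, and with the block Fdps and Hmgcs1 were called (limma adjusted p = 0.0084 and 0.013). Without PLKO 2 the median of this list was -0.004 (camera adjusted p = 0.52), without PLKO 3 it was 0.77 (2.73e-06) and without KD 3 it was 0.39 (0.17). Its call was also lost with array weights (median 0.30, adjusted p = 0.096) and with voom and quality weights (0.35 and 0.061, or 0.28 and 0.059 with total library sizes). All 7 replication-dependent histone genes tested were lower, with a median of -2.16 (camera adjusted p = 0.015, adjusted p = 0.92 with an estimated correlation). None was called over all genes, 2 were adjusted over the list alone and 6 with the replicate block. Hist2h3c2, Hist1h1e, Hist1h2bc and Hist1h2bg had log2 fold changes of -2.70, -2.16, -2.23 and -2.38, on few reads apart from Hist1h2bc, with limma adjusted p from 0.062 to 0.16 and, with the block, of 0.0056, 0.010, 0.0051 and 0.0030. Near-identical histone copies can share reads. Without PLKO 3 the median of the histone list was -1.56 and its camera adjusted p 0.18. Without KD 1 the median was -1.14 (0.014), with quantile normalization -1.25 (0.015) and on the log2(FPKM + 1) scale -1.24 (0.013).

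None of these 4 list calls held with an estimated correlation (0 lists at an unadjusted p under 0.05) or with fry (adjusted p from 0.28 to 0.72). Over all alternatives the adjusted p ran from 2.73e-06 to 0.92 for the stress response and the cholesterol lists, from 2.74e-06 to 0.92 for immediate early genes and from 7.75e-05 to 0.92 for the histones.

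**Figure D3:**
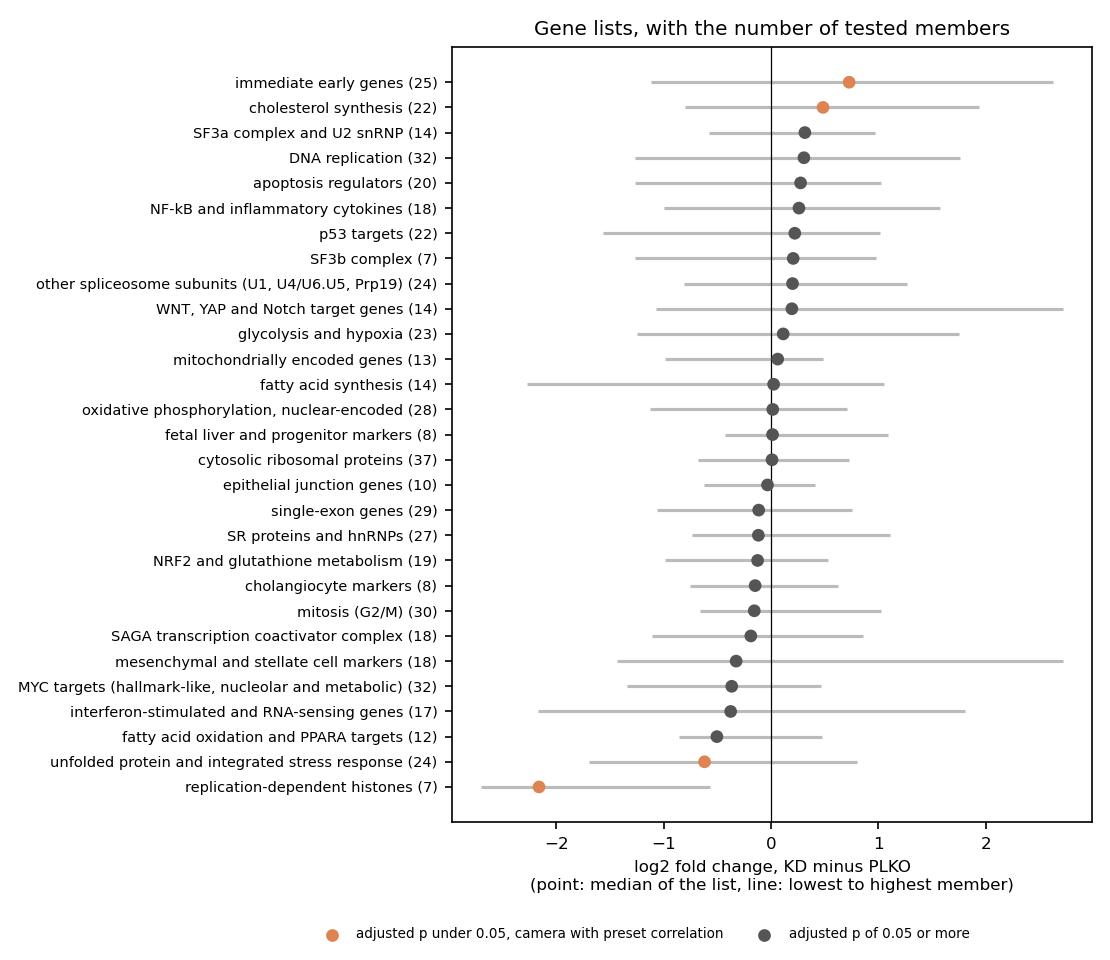
Median log2 fold change (KD minus PLKO, points) of the 29 tested gene lists, with lines from the lowest to the highest member and the number of tested members in brackets. Orange points mark the 4 lists with a camera adjusted p under 0.05 at the preset correlation, from histones (-2.16) to immediate early genes (0.73).

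Other parts of the splicing machinery held no member called over all genes. The 14 genes of SF3a and the U2 particle had a median log2 fold change of 0.32, with Ddx46 at 0.97 (limma adjusted p = 0.059, the 1 member called adjusted over the list alone and with the block, adjusted p = 0.018). Of 24 other spliceosome subunits, 2 were higher and 1 lower adjusted over the list alone. With the block, which called 2080 of all 10770 tested genes, 3 were higher and 1 lower. Ddx23 had a log2 fold change of 1.27, Prpf8 of 0.91 and Prpf31 of -0.81, called with the block (limma adjusted p = 0.0093, 0.018 and 0.026). Of 27 SR proteins and hnRNPs, 2 were higher and 1 lower adjusted over the list alone (2 and 2 with the block), with Ptbp2 at 1.11, Srsf4 at 0.79 and Hnrnpm at -0.71 (limma adjusted p = 0.017, 0.028 and 0.034 with the block). The SAGA coactivator complex, in which SF3B3 is also found, had 1 of 18 members called: Taf12 fell from 12.4 ± 2.43 to 5.69 ± 0.614 FPKM (-1.11, limma adjusted p = 0.044), and adjusted over the list alone 2 members were lower (1 higher and 2 lower with the block). Of 29 tested genes listed as single-exon, 19 have 1 exon in the annotation, 9 have more and 1 was not matched. The 1 called, Arf6 at -1.06 (limma adjusted p = 0.046), has 2 annotated exons, and none of the 19 was called over all genes. In the whole list 3 members were lower adjusted over the list alone and 4 with the block. The camera adjusted p of the SF3b list and of these lists ran from 0.23 to 0.88. Without KD 3 it was 0.045 both for SF3a with the U2 particle and for the other spliceosome subunits, with medians of 0.56 and 0.34, against 0.32 and 0.20 with all libraries and 0.14 and 0.04 without KD 1 (0.58 and 0.63).

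Few FXR target and hepatocyte genes could be tested. Most of them were missing from the 11866 listed genes, by a filter that is not given. Only 63 (KD 3) to 336 (PLKO 2) listed genes had under 10 reads in a library. Few reads in these cells may thus explain the absence, but the values of the missing genes could not be checked. Of 27 FXR target and bile acid genes 5 were listed and 4 tested. These were Pltp, Fetub, Sdc1 and Rxra, with log2 fold changes of -1.47, -1.81, -0.40 and 0.08. None was called over all genes. Pltp and Fetub were lower adjusted over the list alone and with the replicate block (limma adjusted p = 0.0062 and 0.0041 with the block). Of 30 hepatocyte identity genes 4 were listed and 3 tested, Rbp4, Apoe and Foxa1. None was called, adjusted over the list alone and with the block included. MYC targets had a median of -0.37, with 24 of 32 members lower. Shmt2, the mitochondrial serine hydroxymethyltransferase, fell from 97.5 ± 21.7 to 38.0 ± 3.49 FPKM (-1.34, limma adjusted p = 0.033), as the 1 member called over all genes and adjusted over the list alone, with 4 under the block. The camera adjusted p of the MYC list was 0.096, but 0.0019 without PLKO 1 and 0.014 without KD 1, with medians of -0.50 and -0.39. Without PLKO 2 its median was -0.14 (0.52), and over all alternatives the adjusted p ran from 0.0019 to 0.92.

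Neither cell cycle list passed the camera test. DNA replication genes had a median of 0.31, with 21 of 32 members higher (camera adjusted p = 0.19). Without KD 1 the median was 0.007, with 16 of 32 higher (camera adjusted p = 0.74). The list passed without PLKO 1 (median 0.39, adjusted p = 0.0070), without KD 3 (0.53, 0.0049), without both libraries numbered 3 (0.43, 0.016) and with the block and the trends of length, exon number and GC content removed (0.34, 0.023), and over all alternatives its adjusted p ran from 0.0049 to 0.92. Prim1, the primase subunit, fell from 21.5 ± 5.37 to 8.81 ± 1.33 FPKM (-1.27, limma adjusted p = 0.040). It was the 1 call over all genes and adjusted over the list alone, with 5 higher and 2 lower under the block. Mcm3 and Pcna had log2 fold changes of 1.76 and 1.05, called with the block (limma adjusted p = 0.0042 and 0.017). No mitosis gene among 30 was called over all genes or adjusted over the list alone (3 higher with the block, such as Cdk1 at 0.82, limma adjusted p = 0.032). Of 22 p53 targets Mdm2, with 1395, 1301 and 1328 reads in PLKO and 2806, 2337 and 2516 in KD, was the 1 that changed (log2 fold change 0.98, SE 0.19, limma adjusted p = 0.043). Adjusted over the list alone 2 p53 targets were higher and 1 lower (4 and 2 with the block), among them Rrm2b at -1.56 (limma adjusted p = 0.051, and 0.011 with the block). None of 20 apoptosis regulators was called over all genes or adjusted over the list alone, against 3 higher and 2 lower with the block. Cflar stood at 1.02 and Bad at -0.85 (limma adjusted p = 0.018 and 0.021 with the block). The camera adjusted p of the mitosis, p53 and apoptosis lists was 0.88, 0.27 and 0.28.

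Interferon-stimulated genes included 3 that fell. Isg15 went from 10.2 ± 3.14 to 3.35 ± 0.682 FPKM (-1.58, limma adjusted p = 0.038), Usp18 from 2.76 ± 0.601 to 0.747 ± 0.215 FPKM (-1.91, adjusted p = 0.044), and Ifi44 is given above. On the log2(FPKM + 1) scale Usp18 fell by 1.10 (adjusted p = 0.039). Of 17 tested members, 2 were higher and 6 lower adjusted over the list alone and with the block, and the camera adjusted p was 0.17. Of 18 genes of NF-kB and inflammation none was called over all genes, with 1 higher and 1 lower adjusted over the list alone and 6 and 2 with the block. Lif and Tnfaip3 had log2 fold changes of 1.18 and 1.57 and Relb of -0.76, called with the block (limma adjusted p = 0.012, 0.0026 and 0.032). The camera adjusted p of that list was 0.27, and 0.035 without PLKO 1 or 0.019 without KD 1, with medians of 0.49 and 0.48. Its median of 0.26 was 0.14 without PLKO 2 (0.52) and 0.11 without KD 2 (0.48), and over all alternatives its adjusted p ran from 0.019 to 0.92.

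Among cell type markers, Cd44, a progenitor marker, rose from 37.8 ± 8.89 to 79.8 ± 12.6 FPKM (1.09, limma adjusted p = 0.048). It was the 1 of 8 fetal liver and progenitor markers called, with 3 higher adjusted over the list alone and with the block, Hmga2 and Igf2bp1 both at 1.09 (limma adjusted p = 0.0071 and 0.012 with the block). S100a8, a myeloid calcium-binding protein, had 8 reads in PLKO and 104 in KD (ratio 13.5, counting interval 6.59 to 32.1, limma adjusted p = 0.036), and on the log2(FPKM + 1) scale a log2 fold change of 1.55 (adjusted p = 0.039). It was the 1 of 4 tested macrophage and leukocyte markers called, with 2 higher adjusted over the list alone and 3 higher and 1 lower with the block. Cd68 stood at 1.76 (limma adjusted p = 0.075, and 0.0018 with the block). Of 18 mesenchymal and stellate cell markers none was called over all genes, while 2 were higher and 5 lower adjusted over the list alone and with the block: Lox, Col3a1 and Pdgfrb had log2 fold changes of -1.41, -1.24 and -0.96, and Ctgf 2.72 (limma adjusted p = 0.0040, 0.0045, 0.012 and 0.0019 with the block). Slc4a2, at -0.75, was the 1 of 8 cholangiocyte markers lower adjusted over the list alone and with the block (limma adjusted p = 0.032). No epithelial junction gene of 10 and no endothelial gene passed in any of these counts, the endothelial list having 1 tested member, Flt1, at -0.38. The camera adjusted p of the progenitor, mesenchymal, cholangiocyte and epithelial lists was 0.32, 0.35, 0.88 and 0.88.

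Of 14 targets of WNT, YAP and Notch, Amotl2 rose from 18.1 ± 0.590 to 39.1 ± 1.57 FPKM (1.11, SE 0.18, limma adjusted p = 0.032). Adjusted over the list alone and with the block 3 members were higher and 1 lower, Ankrd1 at 1.67 and Tcf7 at -0.89 among them with limma adjusted p of 0.0021 and 0.017 under the block (camera adjusted p = 0.29).

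In energy metabolism Pgam1, a glycolytic mutase with many processed copies that can share its reads, rose from 103 ± 27.0 to 339 ± 29.7 FPKM (1.75, SE 0.23, limma adjusted p = 0.029). It was the 1 of 23 glycolysis and hypoxia genes called over all genes and adjusted over the list alone, with 2 higher under the block, and the camera adjusted p was 0.22 (0.00030 without KD 1, with a median of 0.46). The median of that list was 0.11 with all libraries, -0.06 without KD 3 (0.93) and -0.16 without both libraries numbered 3 (0.91). Of 14 fatty acid synthesis genes Dgat2 was the 1 called, with 2 higher and 1 lower adjusted over the list alone and with the block, Elovl6 at 1.05 and Fasn at 0.76 (limma adjusted p = 0.012 and 0.035 with the block). Of 12 genes of fatty acid oxidation none was called over all genes or adjusted over the list alone, and 2 were lower with the block, Hadha at -0.86 and Acadvl at -0.84 (limma adjusted p = 0.020 and 0.023). Nuclear-encoded genes of oxidative phosphorylation (28 tested) had 1 member lower adjusted over the list alone, Ndufs1 at -1.13 (limma adjusted p = 0.0502, and 0.0084 with the block), and 1 higher and 1 lower with the block. None of 13 mitochondrially encoded genes passed in any of these counts. Of 37 cytosolic ribosomal protein genes none was called over all genes or adjusted over the list alone, with 1 higher and 1 lower under the block, the higher one being Rps2 at 0.73 (limma adjusted p = 0.036). None of 19 NRF2 and glutathione genes was called over all genes or adjusted over the list alone, and 2 were lower with the block, Gsta4 at -0.99 and Hmox1 at -0.84 (limma adjusted p = 0.032 and 0.048). The camera adjusted p of these lists other than glycolysis was 0.29 for fatty acid oxidation and 0.88 for the rest. Median, mean and camera direction differed in sign for the fatty acid synthesis, oxidative phosphorylation, mitochondrially encoded, mitosis and epithelial lists, whose medians and means lay between -0.16 and 0.06.

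The libraries numbered 3 stood apart in both groups. The first principal component of log2 FPKM (50.8% of the variance) separated KD from PLKO, with KD 3 nearest to the controls. The second (31.2%) separated PLKO 3 (-39.0) and KD 3 (-37.3) from the other libraries. On it PLKO 2 lay about as far out on the opposite side (38.4), with PLKO 1, KD 1 and KD 2 at 18.1, 13.3 and 6.4. KD 3 correlated over genes with PLKO 3 at r = 0.956, with KD 1 at 0.914 and with KD 2 at 0.944. Genes are not independent replicates, and these correlations describe the libraries only.

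**Figure D4:**
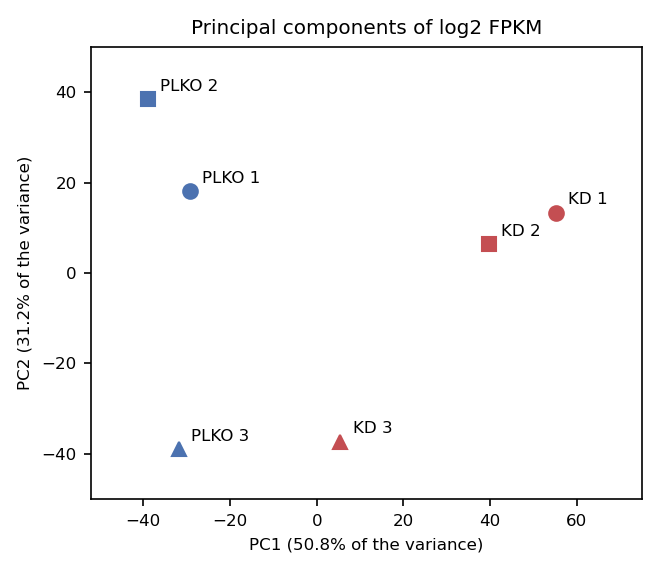
The 6 libraries on the first (x axis, 50.8% of the variance) and second (y axis, 31.2%) principal components of log2 FPKM over 10770 genes, PLKO in blue and KD in red, with marker shapes for the library number. PLKO 3 and KD 3 lie near -39 and -37 on the second component. The other 4 libraries lie above 0, from 6.4 (KD 2) to 38.4 (PLKO 2).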

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

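Of the alternatives, log2(FPKM + 1), the limma-voom fits, leaving out both libraries numbered 3 and the trend removals were chosen after seeing the data. Sf3b3 was lower in KD under all 25 alternatives with a fit (log2 fold change -1.43 to -1.15), and lost its call without PLKO 1, PLKO 2, KD 1 or KD 2. With 1 library left out in turn its log2 fold change ran from -1.43 to -1.15, the count of changed genes from 0 to 1751, that of genes changed at least 2-fold from 0 to 1264 and that of shifted lists from 3 to 7. The replicate block gave 2080 changed genes and 1088 at least 2-fold, kept all 314 calls and the 4 list calls, and with the trends removed gave 2230 and 1036. Limma without the trend gave 151 and 151. Array weights gave 6030 and 1443, but the weights had not converged and rested on KD 2 (weight 44.7, others 0.21 to 1.94). They also turned mt-Atp8 from -0.99, not called, to 2.45. Voom with quality weights gave 3729 and 1388, or 4114 and 1454 with total library sizes, with KD 2 again weighted most (5.70, others 0.37 to 1.42). Leaving out both libraries numbered 3 gave 3000 and 1801. Other pseudocounts, filters and scalings, robust variances, unweighted voom, log2(FPKM + 1) and removal of trends alone gave 220 to 369 changed genes. Camera with an estimated correlation and fry shifted 0 lists (0 and 4 at an unadjusted p under 0.05). Except where the weights are named, the cause was not tested. Over all alternatives, named genes kept their side of the threshold 2945 times, lost a call 163 times, gained one 578 times and reversed once, and lists did so 756, 15, 11 and 0 times. Depth limits genes with few reads, such as Colec11 with 4 reads in PLKO.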

Other observations

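The tests of a difference shared by the libraries numbered 3, of RNA without poly(A) tails, of S phase and of exon number were chosen only after the result was seen, and Lars, Aldh18a1, Asns, Atf4, mt-Rnr2 and Hist1h1c stand outside the rule for named genes and were chosen after their values were seen. The lists of synthetases were written after the fall of Lars was seen, and before the fold change of any of their members except the mitochondrial Mars2 (-0.82) was. The members named here were picked from the results. Aminoacyl-tRNA synthetases charge tRNAs with amino acids. All 12 cytosolic synthetases listed as ATF4-responsive (Lars left out, other cytosolic synthetases not examined) had negative log2 fold changes, with a median of -0.96 and a range from -1.43 to -0.62. Limma called 4 of them, Sars, Eprs, Iars and Cars, and 10 with the replicate block. Their camera p was 2.48e-07 with the preset correlation and 0.063 with an estimated one. The 17 mitochondrial synthetases had a median of -0.20, with 12 lower, 1 called, Rars2, and 4 with the block. Their camera p was 0.025, also downward, with the preset correlation and 0.24 with an estimated one. Lars and Aldh18a1, which makes the precursor of proline, fell by 1.76 and 1.95 on the log2 scale (limma adjusted p = 0.022 for both).

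Lower activity of the transcription factor ATF4, which drives genes of amino acid supply, is a candidate explanation for the fall of Atf5, Aldh1l2, Gpt2, Pycr1, Slc7a5, Lars and Aldh18a1. These 7 genes were grouped after their fall was seen, with no list fixed beforehand and no enrichment test. The test on the synthetases could have failed: the ATF4-responsive median was -0.964, below the mitochondrial one by 0.76, with a one-sided permutation p of 0.0013 over 100000 reassignments of genes to the lists, genes not being independent. The lists also differ in compartment, cytosol against mitochondria, so the contrast does not isolate ATF4. A trend with exonic length, exon number or GC content is argued against, since its removal left the median of the 7 genes at -2.22 (-2.19 before) and all 7 called, and with the replicate block too. Against a uniform fall of ATF4 targets, Asns had a log2 fold change of -0.39 (limma adjusted p = 0.39). The Atf4 transcript had one of -0.37 (limma adjusted p = 0.42), which does not measure the activity of the protein. A part of MYC, whose transcript had a log2 fold change of -1.29 that was not called (-0.68 without PLKO 2), was not tested and stays open.

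PLKO 3 and KD 3 stood apart from the libraries numbered 1 and 2. Their deviations from the other libraries of their groups correlated over genes at r = 0.497, but this is the correlation by which they were seen to deviate together, so it decides nothing, and a difference shared by the libraries numbered 3, such as a day of culture or extraction, stays open. No label names one. The slope of pair 3 on pair 1 was 0.437 times that of pair 2 on pair 1, which repeats the distances on the first principal component (37.3 in pair 3 and 78.6 in pair 2), so a smaller effect of the knockdown in KD 3 stays open too. Sf3b3 itself stood at 45.6%, 33.3% and 47.7% of the PLKO library of the same number in pairs 1, 2 and 3. Relative to the PLKO mean it stood at 38.4%, 35.6% and 51.8% in KD 1, 2 and 3. By both measures it was lowered least in KD 3, though by the first only slightly less than in KD 1. Control cells mixed into KD 3 could not be excluded. Genes that rose at least 4-fold in pairs 1 and 2 (89 genes) needed a median control share of 0.47. Genes that fell (43 genes) needed one of 0.21. The difference of 0.257 passed the limit against mixing that was written before this test. Its 95% bootstrap interval (0.10 to 0.39) also held values below that limit. The written limit had not asked for the interval to pass, and the outcome is taken as undecided for caution. The genes were chosen by libraries that also enter the shares, so shares above 0 need no mixing.

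The 7 histone genes had a median log2 fold change of -2.16, with no member called over all genes and a list call that was lost with an estimated correlation (adjusted p = 0.92), with fry (0.28) and without PLKO 3 (0.18, median -1.56). Without KD 1 the median was -1.14 (0.014). Its adjusted p ran from 7.75e-05 to 0.92 over all alternatives. In contrast mt-Rnr2, the mitochondrial large ribosomal RNA, rose 6.01-fold (log2 2.59, limma adjusted p = 0.031). A different yield of RNA without poly(A) tails would move such RNAs one way. Histones minus mt-Rnr2 came to -4.75, but this opposite movement prompted the question, the histone call is not firm, and 6 of 8 snoRNA genes were higher (median 0.55) as mt-Rnr2 was, so it stays open. Fewer cells in S phase, when histone genes are expressed, might lower them. DNA replication genes had a median of 0.306 (95% bootstrap interval over genes 0.002 to 0.56). With 1 library left out in turn it ran from 0.007 without KD 1 (-0.15 to 0.17, 16 of 32 higher) to 0.53 without KD 3. None of these fits showed a fall of these genes near that of the histones. How closely these genes, or histone reads captured by poly(A), follow S phase was not measured. Genes are also not independent, and 11 of 32 were lower. Fewer cells in S phase therefore stays open, as the whole cause or as a part. Reads of Hist1h1c were 3662, 3749 and 10299 in PLKO and 233, 1029 and 6779 in KD, so in this gene the libraries numbered 3 differed from the others of their group by as much as the groups did, and a cause shared with that pattern stays open.

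Whether genes with more exons fall after knockdown of a splicing factor stays open. Spearman's rho of fold change on exon number over genes was -0.08 and -0.09 in pairs 1 and 2 of libraries, 0.087 in pair 3 and -0.05 over all libraries. Protein-coding genes with 21 or more exons had a median log2 fold change of -0.13, against -0.07 to 0.01 for those with fewer. Pair 3, the pair that goes the other way, holds the libraries that stand apart, and 1 pair excludes nothing.

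The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 314 genes and 297 at least 2-fold, and the highest of the other splits called 0 and 0 (1492 genes at an unadjusted p under 0.05 at most), so 1 of the 10 splits gave counts as large in each case. The other 3 splits that part all 3 numbered pairs also called 0. All splits but the real one hold KD and PLKO libraries on both sides, so a group difference adds to their residual spread. Their counts of genes are thus lowered and are no measure of what chance gives. For lists the order was the other way: the real split shifted 4 lists, 9 of the 10 splits shifted at least as many, and the highest other, PLKO 1, KD 2 and KD 3 against the rest, shifted 17. That points to a structure of the samples in which genes of a list move together, and camera with the preset correlation of 0.01 does not allow for it.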
